A study of Homo sapiens with 20 samples.

How the data were processed

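Gene expression was measured in MDA-MB-231 cells, an established human breast carcinoma line of mesenchymal character, on 1-colour Agilent whole-genome arrays. Per the labels, each of 20 samples was amplified RNA labelled with the dye Cy3 and hybridised to its own array. The 4 groups cross the surface on which the cells were plated overnight (gelatin, which is denatured collagen, or HDFC, a dense layer of fibrillar collagen) with the medium (with or without serum). Each group holds 5 samples, numbered 1 to 5 as repeats, and the labels do not say whether the repeats were separate cultures. The p-values given for these data therefore measure only the spread between these samples, which may be technical. Groups and repeat numbers were taken from the labels. The file headers place the 20 arrays on 5 slides read in 5 scans, with the 4 arrays of each repeat on 1 slide. Every group occupied 1 fixed position on each slide, so that position and group cannot be told apart.

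Per the file headers, spot brightness was read with Agilent Feature Extraction 9.5.3.1, whereas the submitters' processing notes name version 9.1. The deposited scanner files hold the processed signal of each spot as an intensity on a linear scale, after background subtraction and spatial detrending, and not normalised between arrays. They also hold the mean spot intensity and the local background intensity, and 0 or 1 flags for spots well above background, saturated spots and outlier spots. The authors also deposited a table of log2 values for the same arrays, whose scale, centring and direction are not stated. Each column of that table had a median of 9.21 and correlated with its own array at r of at least 0.997 before centring and 0.993 after centring each gene, against at most 0.789 with any other array. Higher therefore means brighter, and the scale is log2 from 3.09 to 18.6. The submitters' processing notes name RMA, and the steps behind that table beyond this name are not given in the sources used here. Of its rows, 30870 were used, 7493 of them joining several probes, and 2 empty or repeated rows were left out.

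From the scanner files, log2 of the processed intensity was taken and the 75th percentile of each array was subtracted, so that levels below are log2 relative to that percentile. Control spots were left out, as were 1435 values of tested genes marked as outlier spots, and saturated spots were kept. Of 45015 spots per array, 43376 were not controls and represented 41000 probes. A probe was kept if it lay well above background on at least 4 of the 5 arrays of at least 1 group, which left 31951 probes. Of several probes of a gene, the brightest over all 20 arrays represented it, which was a choice among probes for 6385 genes. This left 23308 genes and unnamed transcripts, of which 15628 carried a matched gene symbol. Probes were named through the accessions in the files with a table of RefSeq genes of assembly GRCh38.p14, used for names alone. By this route 23434 probes were named by accession, 5415 by Entrez number, 148 by a current symbol and 144 by an older one. The other 11859 probes kept the name in the file. Where accession and Entrez number both matched, they gave different genes for 27 of 23345 probes. Probe coordinates are those of the array annotation on build hg17, as the files give them.

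Signal was ample on all arrays. The 75th percentile of intensity lay between 3897 and 10930, between 70.5% and 83.5% of the probes were well above background, and at most 3 probes were saturated on an array. The number of arrays limits the precision, with a median standard error of a log2 change of 0.25 over all genes for each 2-group comparison. This value is the same throughout because the 4 groups share 1 estimate of the spread. The median SD of a gene within its group was 0.508 for HDFC without serum. It was 0.288 for gelatin without serum, 0.269 for gelatin with serum and 0.359 for HDFC with serum. The shared estimate thus tends to be too low for 2-group comparisons that use the HDFC no-serum arrays, and too high for serum on gelatin. A probe not well above background on any array of a group has only a bound there. Its change is then given as "at least N-fold", the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the probe's own level and the lowest level among probes well above background.

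Before the data were examined, the following choices were made. The fit was limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3 with the package data.table, version 1.17.8) of all 20 arrays with 1 mean per group and no block, and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. The 5 comparisons were HDFC against gelatin without serum and with serum, serum against no serum on gelatin and on HDFC, and the interaction, which is the HDFC response with serum minus that without. For each of these but the interaction, the genes named were the 8 largest rises and 8 largest falls among genes past the threshold that carried a symbol and moved the same way in all 5 repeats. For the interaction, the 5 largest of each sign past the threshold were to be named. For each of 30 lists of known genes, up to 3 members past the threshold with the smallest adjusted p were also named. A gene that this rule names is not reported here. The lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over the 30 lists, and again with the correlation estimated for each list. They were also tested with fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Counts of list members are given over all genes tested and adjusted over the list alone. Of the lists, 4 served as controls, with markers of fibroblasts, of leukocytes, of endothelium, and of luminal and basal breast epithelium. The final one covers the tissue of this breast carcinoma line, so it is not a list of another cell type.

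The repeat number was tried as a block. The deviations of the arrays from their group means correlated at r of 0.24 to 0.737 (median 0.479) over the 30 pairs of arrays of the same repeat, against a median of -0.126 over 120 pairs of different repeats. Each of the 20 arrays correlated best with an array of its own repeat, and duplicateCorrelation gave 0.403. The numbers therefore pair the samples, and the pairing coincides with slide and scan. The block lowered the median standard error from 0.25 to 0.183 without serum. Blocked values stand beside a result where they change a call or move a count of calls over all genes by more than 1.5 times, and counts adjusted over a list alone are given without the block.

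Other alternatives were quantile normalisation, normexp background correction of the mean intensity with an offset of 50 followed by quantile normalisation, the authors' log2 table, no filter and a stricter filter on dim probes, and a fit of the arrays of each comparison alone. A fit of each probe, a random block, array weights, and leaving out each repeat and each single array were also run. After the data had been seen, fits without the HDFC no-serum array of repeat 4 with and without the block, a fit of the interaction to the 10 matrix differences within repeats, and the lists under normexp and under the omissions were added.

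The fits were tested on simulated data made from all 23308 genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For HDFC against gelatin without serum, the fit without a block recovered 3.0%, 37.3% and 84.8% of them, and the blocked fit 31.3%, 65.7% and 92.4%. With serum the fit without a block recovered 3.0%, 29.9% and 83.3%. For serum it recovered 4.5%, 29.9% and 90.9% on gelatin, and 1.5%, 31.3% and 81.8% on HDFC. The interaction was the hardest to detect, with 0%, 1.5% and 62.1% recovered. The fit without a block called 0 unchanged genes in these 5 simulations. The blocked fit called 8, 2, 2, 23 and 4. When 1 list of 35 genes was raised by 0.5 in 20 simulations of HDFC against gelatin without serum, camera with either correlation and fry called it in all 20, and camera with the preset correlation called 1 of 580 lists left unchanged. The noise was drawn independently for each gene, so these simulations do not show how often lists whose members vary together are called. When the real arrays of that comparison were regrouped at random, camera with the preset correlation called a median of 7 of the 30 lists, and at most 15.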

Results

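The expression of 23308 genes and unnamed transcripts was compared between MDA-MB-231 cells on gelatin and on HDFC, a dense fibrillar collagen matrix, each with and without serum, with 5 arrays per group. MDA-MB-231 is an invasive breast carcinoma line that lacks the oestrogen receptor, and gelatin is collagen that has lost its fibrillar structure. The series is about a signature of the response of carcinoma cells to extracellular matrix, so the comparisons of HDFC with gelatin ask which genes respond to the matrix. The comparisons of serum with no serum ask which genes respond to serum on each surface. The 75th percentile of intensity lay between 3897 and 10930 on the 20 arrays, and at least 70.5% of the probes were well above background on each. The lowest of these intensities belonged to the HDFC no-serum array of repeat 4. That array deviated from its group mean with an SD of 0.975 (log2) over all genes, against 0.28 to 0.589 for the other 19 arrays. Position on the slide was the same for all 5 arrays of a group and cannot be told apart from the group in any comparison.

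Without serum, 68 genes were higher and 220 lower on HDFC than on gelatin. FST, which encodes follistatin, a secreted antagonist of activins, rose 3.15-fold, from 0.18 ± 0.39 on gelatin to 1.84 ± 0.48 on HDFC (log2 relative to the 75th percentile of the array, SD, n = 5 each; adjusted p = 0.00522). Its probe lies on chromosome 5 at 52816594 to 52816653 (hg17). ADAMTS6, a secreted metalloprotease, rose 4.14-fold, from -1.61 ± 0.34 to 0.44 ± 0.56 (SD, n = 5 each), and PDE1C, a calcium-dependent phosphodiesterase, rose 4.50-fold (log2 change 2.17 ± 0.33, SE). Among the falls, GDF15, a secreted member of the TGF-beta family induced by cellular stress, dropped from 3.96 ± 0.76 to 1.59 ± 1.11 (SD, n = 5 each), a change of 5.15-fold. SNED1, an extracellular matrix glycoprotein, fell by 2.71 on the log2 scale and was well above background on 1 of 5 HDFC arrays and all 5 gelatin arrays.

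**Figure D1:**
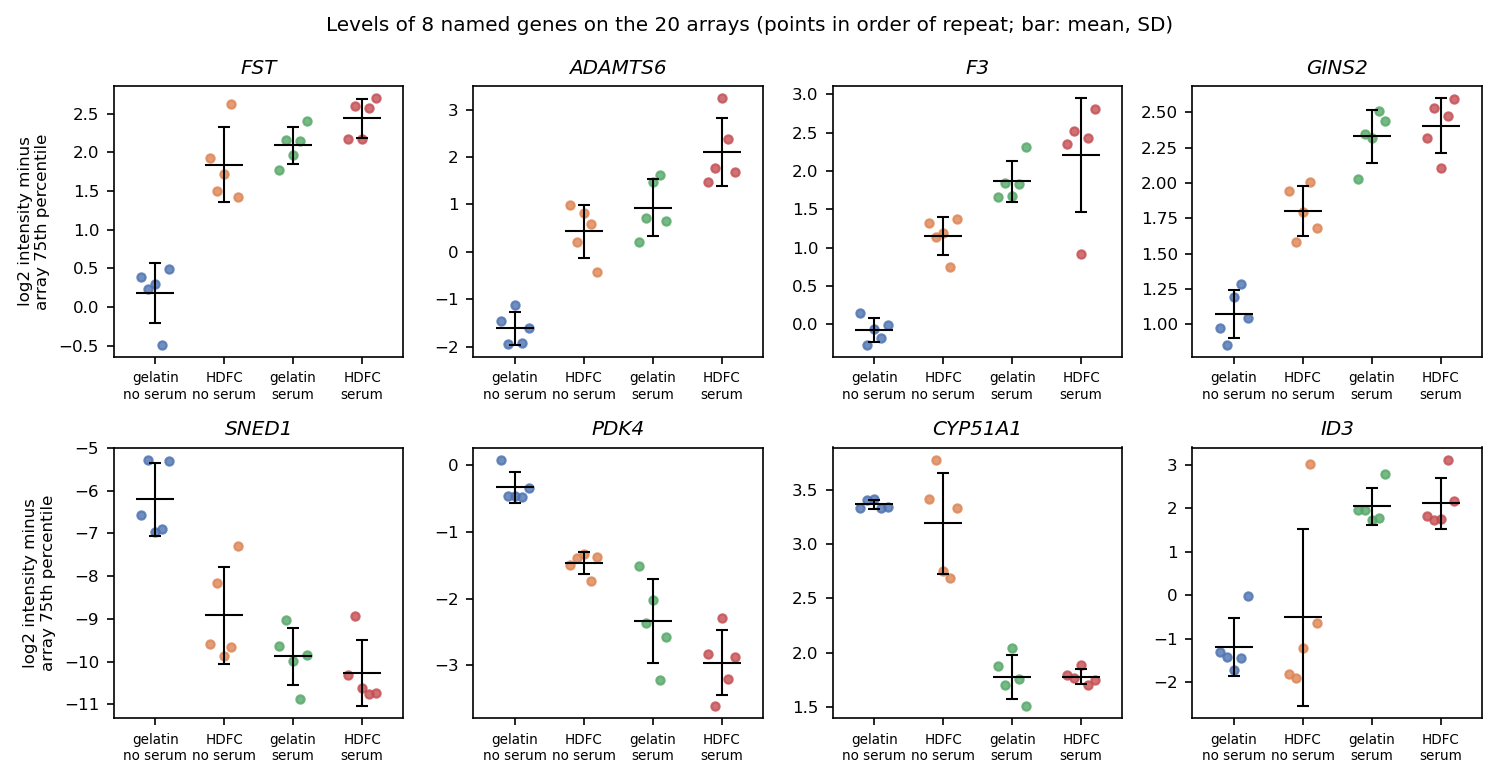
Levels of 8 genes (log2 intensity minus the 75th percentile of the array) on the 20 arrays, with points for the 5 repeats and bars for the mean and SD of each group. FST and ADAMTS6 lie higher on HDFC than on gelatin without serum (3.15-fold and 4.14-fold), and CYP51A1 lies lower with serum on both surfaces (3.00-fold on gelatin and 2.66-fold on HDFC).

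The other largest rises were TSPAN2, a tetraspanin, at 6.28-fold (well above background on 4 HDFC arrays and 1 gelatin array), RIMS2 at 3.39-fold, AOX1, an aldehyde oxidase, at 3.28-fold, HHIP, a binder of hedgehog ligands, at 2.88-fold, and ST6GALNAC5, a sialyltransferase, at 2.85-fold. The other largest falls were PKNOX2, a homeodomain transcription factor, at 9.90-fold, LAIR2, a soluble collagen-binding receptor, at 7.91-fold, and LEFTY1, a secreted antagonist of Nodal, at 7.47-fold. ASB2 fell 6.22-fold, P2RY6, a receptor for uridine nucleotides, 5.42-fold, and SLITRK6 5.31-fold. LAIR2, P2RY6 and SLITRK6 were well above background on 4 of 5 HDFC arrays and LEFTY1 on 3. Each of these genes moved the same way in all 5 repeats, as the rule for naming them required. On gelatin, single arrays stood apart for FST (repeat 4, low) and ASB2 (repeat 1, low).

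Genes of the G1-S transition and DNA replication were higher on HDFC without serum. GINS2, a subunit of the replicative helicase complex (1.66-fold), CDC6, a replication licensing factor (1.74-fold), and RFC3, a subunit of the clamp loader (1.71-fold), rose, and 32 of the 35 members did not pass the test over all genes. Adjusted over the list alone, 23 rose, and with the repeat as a block 19 rose over all genes. The estimates of 34 members were above 0, and the median change was 0.54 (camera adjusted p = 5.31e-18). Within the 5 slides the median was 0.63, 0.49, 0.52, 0.88 and 0.17. Targets of YAP and TAZ, transcriptional coactivators that respond to cell tension and spreading, were higher too, with a median change of 0.40 (camera adjusted p = 9.57e-08). F3, which encodes tissue factor (2.34-fold), ANKRD1 (2.48-fold) and CCN2, connective tissue growth factor (1.94-fold), rose among 24 members, 11 rose adjusted over the list alone, and 8 rose with the block. The call of CCN2 ended under each of the 3 other scalings and without 13 of the 20 single arrays. The camera calls of these lists held with an estimated correlation (adjusted p = 0.0408 for both). With the block and an estimated correlation they did not (adjusted p = 0.201 for G1-S and 0.229 for YAP-TAZ).

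Genes of mitosis and of ribosome biogenesis lay above 0 without a single member past the limma threshold over all genes. All 32 mitotic genes had estimates above 0, with a median of 0.41 (camera adjusted p = 1.18e-12, and adjusted p = 0.136 with an estimated correlation). Of these 32 genes, 17 had an unadjusted p under 0.05, 6 rose adjusted over the list alone and 7 rose with the block. Of 29 genes of ribosome biogenesis and MYC targets, 27 lay above 0, with a median of 0.37 (camera adjusted p = 2.3e-10, and adjusted p = 0.0965 with an estimated correlation). Of these, 13 had an unadjusted p under 0.05, 3 rose adjusted over the list alone and 8 rose with the block. FOXO targets and genes of growth-factor withdrawal moved the other way, with a median of -0.57 (camera adjusted p = 1e-04, and adjusted p = 0.261 with an estimated correlation). PDK4, a kinase that inhibits pyruvate dehydrogenase, fell 2.20-fold, 9 of 21 members fell adjusted over the list alone, and 8 fell with the block. On the HDFC no-serum array of repeat 4, the G1-S list lay 0.66 above the mean of the other 4 arrays of its group, the ribosome list 0.89 above and the FOXO list 0.66 below (median deviation -0.66). The camera calls of the G1-S, YAP-TAZ, mitosis, ribosome and FOXO lists were kept without each single array, without each repeat and under each of the other scalings.

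A further 6 lists called without serum each lost the call under at least 1 omission or scaling. The camera adjusted p was 2.75e-05 for immediate early genes, 0.00187 for the interferon list, 0.00235 for heat shock, 0.0207 for fatty acid synthesis, 0.0405 for cholesterol synthesis and 0.0184 for the respiratory chain. Immediate early genes, which respond within minutes to mitogens and stress, had a median of 0.57 with 22 of 25 above 0 (adjusted p = 0.453 with an estimated correlation). Interferon-stimulated genes had a median of -0.35, and MX2, an antiviral GTPase, fell 2.12-fold (adjusted p = 0.361 with an estimated correlation). Without repeat 4 these calls ended, with medians of 0.10 (adjusted p = 0.0801) and -0.27 (0.0613). Without the HDFC no-serum array of repeat 4 alone the immediate early median was 0.16, and without the gelatin no-serum array of repeat 2 the interferon median was -0.23. With the block 9 interferon-stimulated genes fell, against 1 without it and 2 adjusted over the list alone. Limma called 0 members of the immediate early, heat shock, fatty acid and respiratory chain lists over all genes. At an unadjusted p under 0.05 these lists had 7, 4, 0 and 1 members higher and 0, 1, 4 and 0 lower. Adjusted over the list alone 3, 0, 0 and 0 members passed, and with the block 3, 3, 2 and 1. Heat shock genes (median 0.28, adjusted p = 0.485 with an estimated correlation) lost the call under each other scaling and without the HDFC no-serum array of repeat 4, where the median was 0.11 (adjusted p = 0.129), and their median was 0.16 without the gelatin no-serum array of repeat 1. For fatty acid synthesis (median -0.33, adjusted p = 0.453 with an estimated correlation) the median moved less as the call ended, to -0.27 without the HDFC no-serum array of repeat 4 (adjusted p = 0.103), -0.28 without that of repeat 3 (0.156) and -0.28 without the gelatin no-serum array of repeat 2 (0.0549). For cholesterol synthesis (median -0.25, adjusted p = 0.62 with an estimated correlation) the median was -0.08 without the HDFC no-serum array of repeat 4 (adjusted p = 0.807) and -0.38 without that of repeat 5, and the adjusted p was 0.0828 with the block. The call also ended without the HDFC no-serum array of repeat 3 (-0.20, adjusted p = 0.215), the gelatin no-serum arrays of repeats 2, 3 and 4 (-0.25, -0.18 and -0.19, adjusted p = 0.0619, 0.0798 and 0.104) and the HDFC serum array of repeat 3 (-0.25, 0.0564). The direction of the mitochondrial respiratory chain list flipped with the scaling, from a median of 0.15 (adjusted p = 0.62 with an estimated correlation) to -0.06 with quantile normalisation. Its median was -0.04 without the HDFC no-serum array of repeat 4 (adjusted p = 0.888) and 0.05 without the gelatin no-serum array of repeat 1 (0.177), and 0.22 without the HDFC no-serum array of repeat 1 (0.00261). On the HDFC no-serum array of repeat 4 the median deviation from the other 4 arrays was 1.72 for the immediate early genes, 0.99 for heat shock, 1.05 for the respiratory chain, -0.69 for the interferon list, -0.39 for fatty acid synthesis and -1.11 for cholesterol synthesis. Among 10000 random lists matched on level, these lay at percentiles 100, 68.96, 97.08, 0.25, 1.76 and 0 in turn.

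Of the 288 genes changed on HDFC without serum, 183 changed at least 2-fold (27 higher and 156 lower), against 679 with the repeat as a block (76 higher and 603 lower). Higher genes made up 23.6% of the calls, against 40.1% with quantile normalisation (136 higher, 203 lower) and 51% in the authors' table (174 higher, 167 lower). With the repeat as a block, 933 genes were higher and 1874 lower, and these included all 288. Without a block the count leaned on single arrays. It was 150, 8, 38, 25 and 96 without the gelatin no-serum array of repeats 1 to 5, and 16, 792, 20, 165 and 618 without the HDFC no-serum array of repeats 1 to 5. It was 151, 158 and 175 without the gelatin serum array of repeats 2, 3 and 5, which enter through the shared estimate of the spread. The arrays of this comparison alone gave 10 genes. Without repeat 1 limma called 0 genes (3150 at an unadjusted p under 0.05), and without repeats 4 and 5 it called 30 and 125. Without repeat 2 the calls were FCGBP, AK124698 and TNFSF4, and without repeat 3 LPL and NR0B2, all lower and chosen after their values were seen. Of the 29 calls of named genes, PDE1C and FST kept theirs without each single array, 23 kept theirs under each other scaling, and 0 kept theirs without each repeat (limma; with the block all 29 passed). Besides CCN2, the call of CXCL1 ended under all 3 other scalings, that of ITGA10 under 2, and those of TSPAN2, LAIR2 and MX2 under 1 each. Calls of LEFTY1, TSPAN2, RFC3 and LAIR2 ended without 17, 16, 16 and 15 of the 20 single arrays. Without the HDFC no-serum array of repeat 4 the falls of LAIR2, LEFTY1 and ASB2 were 4.88-fold, 4.89-fold and 3.85-fold in size, and without that of repeat 3 TSPAN2 was 4.18-fold higher.

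With serum, limma called 0 genes between HDFC and gelatin. At an unadjusted p under 0.05 there were 1063 genes, 4.56% of those tested, where 5% would pass by chance, and the lowest adjusted p was 0.155. With the repeat as a block 2601 genes (11.16%) had an unadjusted p under 0.05, and 2 transcripts fell on HDFC, AL080072 (log2 change -1.36, adjusted p = 0.0145) and ANKRD22 (-2.14, 0.0165). With a random block 5 passed, these 2 with LRRC2 (0.93), MAP2K6, a kinase upstream of p38 (-1.22), and THC2408953 (-2.05). Array weights called 4, LRRC2, AL080072, ANKRD22 and MAP2K6. Without the gelatin serum array of repeat 5 the fit without a block called MAP2K6 alone (-1.37, adjusted p = 0.0394). These genes were chosen after their values were seen. With the block and without the HDFC no-serum array of repeat 4, 95 genes were called (17 higher, 78 lower).

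Among gene lists with serum, camera placed the ribosome biogenesis list higher on HDFC, with 27 of 29 members above 0 and a median of 0.13 (adjusted p = 0.000957, and adjusted p = 0.7 with an estimated correlation). The YAP-TAZ list had a median of 0.16 (adjusted p = 0.0136, and 0.7 with an estimated correlation) and the immediate early genes one of 0.12 (adjusted p = 0.0329, and 0.749 with an estimated correlation). In these 3 lists limma called 0 members over all genes and 0 adjusted over the list alone, and 0, 1 and 2 members had an unadjusted p under 0.05. All 3 camera calls ended without the HDFC serum array of repeat 2 (adjusted p = 0.0581 each), with medians of 0.10, 0.14 and 0.17. Without the HDFC serum array of repeat 5 the YAP-TAZ call (median 0.17, adjusted p = 0.0985) and the immediate early call (0.11, 0.156) ended. The immediate early call also ended under each other scaling and without the HDFC serum array of repeat 1 (median 0.20, adjusted p = 0.0516), and its median was 0.05 without that of repeat 3. The block added the integrin, matrix protein and interferon lists, all lower on HDFC (adjusted p = 0.0494 each), and these calls did not hold with the block and an estimated correlation (adjusted p = 0.801 each).

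The changes on HDFC with and without serum were positively related across genes, which are not independent replicates (Pearson r = 0.527, Spearman rho = 0.461). No array entered both comparisons. Of the 288 genes changed without serum, 272 (94.4%) had the same sign with serum, against 65.3% of all genes. The 68 genes that rose without serum had a median log2 change of 0.90 without serum and 0.29 with serum. The 220 that fell had medians of -1.23 and -0.48. These genes were selected by their change without serum, which tends to enlarge the medians without serum. The smaller medians with serum therefore do not by themselves show a weaker response there. As sets, these genes moved in the same direction with serum relative to other genes (camera p = 0.0282 for the rises and 0.0096 for the falls with an estimated correlation). Within the 5 slides r was 0.327, 0.291, 0.34, 0.182 and 0.022.

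The interaction asked whether the response to HDFC differed between the media. For all 35 G1-S genes the difference, the response to HDFC with serum minus that without, was below 0, with a median of -0.52 (camera adjusted p = 5.68e-21, and adjusted p = 0.0253 with an estimated correlation). Over the 5 repeats the median response of this list was 0.54 ± 0.26 without serum and 0.03 ± 0.03 with serum (SD, n = 5). The 32 mitotic genes also all had negative differences, with a median of -0.45 (camera adjusted p = 7.94e-19, and adjusted p = 0.0791 with an estimated correlation). Their median response was 0.43 ± 0.35 without serum and -0.07 ± 0.14 with serum (SD, n = 5). Differences of the same sign were found for ribosome biogenesis (median -0.29, adjusted p = 3.38e-05, and 0.348 with an estimated correlation) and YAP-TAZ targets (-0.27, adjusted p = 0.000102, and 0.165 with an estimated correlation). FOXO targets differed the other way (0.48, adjusted p = 0.000102, and 0.306 with an estimated correlation). With the block and an estimated correlation the adjusted p for G1-S was 0.119. Limma called 0 single members of these 5 lists over all genes, adjusted over the list alone or with the block, and 11 G1-S, 7 mitotic, 2 ribosome, 4 YAP-TAZ and 3 FOXO genes had an unadjusted p under 0.05. The 5 camera calls were kept without each single array, each repeat and under each other scaling. Without the HDFC no-serum array of repeat 4 the ribosome median was -0.13 and the FOXO median 0.23, and without the HDFC serum array of repeat 3 the FOXO median was 0.28. With the block the interferon list was also called (adjusted p = 0.0411), but not with the block and an estimated correlation (adjusted p = 0.807).

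Immediate early (median -0.39), heat shock (-0.27) and respiratory chain genes (-0.20 and -0.01 in the authors' table, where the direction of the test flipped) were also called for the interaction (camera adjusted p = 0.00715, 0.00432 and 0.00366, and 0.673 each with an estimated correlation). Each of these calls was lost under each other scaling. These calls ended without the HDFC no-serum array of repeat 4, with medians of 0.09, -0.08 and -0.01 (adjusted p = 0.721, 0.392 and 0.705). That of the respiratory chain also ended without the gelatin no-serum array of repeat 1 (-0.10, 0.0716). Of single genes limma called 0 for the interaction, with 551 genes (2.36%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.22. With the block 1630 genes (6.99%) had an unadjusted p under 0.05, and limma called LPL, lipoprotein lipase (1.96, adjusted p = 0.00754). LPL changed by -1.65 on HDFC without serum and by 0.31 with serum, and was well above background on 5 gelatin and 3 HDFC arrays without serum and on 2 and 4 with serum. A fit to the 10 matrix differences within repeats called 3 genes, LPL, KANK4 and SNED1 (adjusted p = 0.0232 each). KANK4 and SNED1 were not well above background on any array with serum, so that their response there has no measured size. Quantile normalisation and the authors' table each called LPL and AK124698, and without the HDFC serum array of repeat 5 LPL was called (2.15, adjusted p = 0.0261). These genes were chosen after their values were seen.

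**Figure D2:**
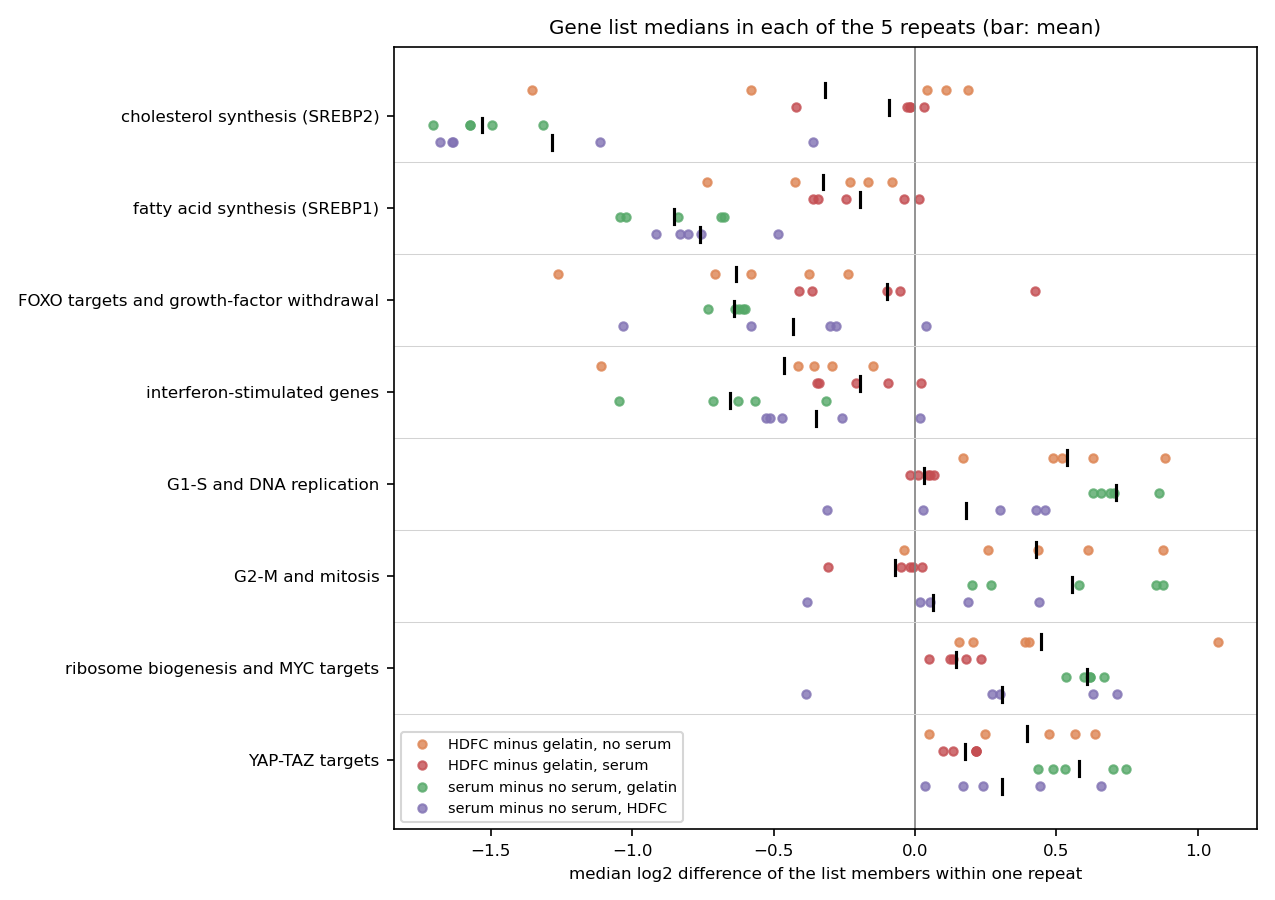
Median log2 change of 8 gene lists in 4 comparisons, with a point for each of the 5 repeats and a bar for their mean. The G1-S list lies at 0.54 ± 0.26 on HDFC without serum and at 0.03 ± 0.03 with serum (SD, n = 5), and the cholesterol list lies below 0 with serum in each repeat on both surfaces.

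On gelatin, serum lowered genes of cholesterol synthesis together. Of 25 members 21 fell, 23 fell adjusted over the list alone, and all 25 estimates were below 0, with a median of -1.56 (camera adjusted p = 8.6e-19, and 0.0319 with an estimated correlation). CYP51A1, the sterol demethylase, fell 3.00-fold (adjusted p = 9.95e-05), FDFT1, squalene synthase, 2.91-fold and LSS, lanosterol synthase, 3.58-fold. Genes of fatty acid synthesis fell too, 9 of 14 over all genes and 11 adjusted over the list alone (median -0.78, camera adjusted p = 7.52e-08, and 0.0332 with an estimated correlation). Among these were ACSS2, an acetyl-CoA synthetase (6.20-fold), LPIN1, a phosphatidate phosphatase (3.31-fold), and FADS2, a fatty acid desaturase (2.41-fold). Within the 5 slides the median of the cholesterol list was -1.57, -1.70, -1.32, -1.57 and -1.5.

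Genes of growth were higher with serum on gelatin. Of the 35 G1-S genes 22 rose (28 adjusted over the list alone, median 0.71), including GINS2 (2.40-fold), RFC3 (2.40-fold) and POLE2, a DNA polymerase subunit (2.50-fold). Of 32 mitotic genes 14 rose (20 adjusted over the list alone, median 0.51), including CDK1, the mitotic kinase (2.07-fold), NUSAP1, a spindle protein (1.99-fold), and AURKB (2.61-fold). Of 29 genes of ribosome biogenesis and MYC targets 13 rose (17 adjusted over the list alone, median 0.60), including ODC1, which makes polyamines (2.30-fold), LYAR (1.73-fold) and NOP2, an RNA methyltransferase (1.5-fold). Of 24 YAP-TAZ targets 10 rose (14 adjusted over the list alone, median 0.55), with F3 at 3.83-fold, ANKRD1 at 3.54-fold and CCN2 at 2.45-fold. The camera adjusted p was 6.99e-19, 4.84e-14, 2.75e-13 and 3.73e-09 for these 4 lists in turn, and 0.0212, 0.0699, 0.0319 and 0.0212 with an estimated correlation, so that the mitotic call did not hold.

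FOXO targets fell with serum on gelatin, 9 of 21 over all genes and 11 adjusted over the list alone (median -0.66, camera adjusted p = 0.000102, and adjusted p = 0.151 with an estimated correlation). They included PIK3IP1, an inhibitor of PI3 kinase (5.26-fold), PDK4 (4.02-fold) and ERBB3, a receptor of the EGF receptor family (2.10-fold). Interferon-stimulated genes fell for 8 of 28 members and 10 adjusted over the list alone (median -0.72, camera adjusted p = 0.00126, and adjusted p = 0.215 with an estimated correlation), with MX2 at 2.59-fold, IRF9 at 1.84-fold and IFITM1 at 1.66-fold. Of 25 autophagy and lysosome genes 8 fell and 10 fell adjusted over the list alone (median -0.25, camera adjusted p = 0.00336, and adjusted p = 0.102 with an estimated correlation). These included WIPI1 (2.38-fold), GABARAPL1 (2.49-fold), both of the autophagosome, and NEU1, the lysosomal sialidase (1.73-fold). Of the 11 lists called by camera, the 9 described here were kept without each single array, each repeat and under each other scaling. With the block and an estimated correlation the adjusted p was 0.161 for cholesterol synthesis and 0.1 for each of fatty acid synthesis, G1-S, ribosome biogenesis and YAP-TAZ targets. With the block 20 ribosome genes rose and 13 interferon-stimulated genes fell, and heat shock genes gained a camera call (adjusted p = 0.0253) that did not hold with the block and an estimated correlation (adjusted p = 0.629).

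Of all genes, 1257 rose and 2356 fell with serum on gelatin, and 1529 of them changed at least 2-fold (329 higher, 1200 lower). INSL4, an insulin-like peptide, rose 9.65-fold (well above background on 2 of 5 no-serum arrays), ID3, an inhibitor of helix-loop-helix transcription factors, 9.31-fold (log2 change 3.22 ± 0.65, SE), TSPAN2 7.95-fold (1 of 5 no-serum arrays) and ND6, a mitochondrially encoded subunit of complex I, 7.62-fold. PDE1C rose 6.58-fold and IL11, a cytokine, 6.47-fold. PDCD1LG2, a ligand of the receptor PD-1, rose at least 2.80-fold and TRPM2, a cation channel, at least 2.65-fold, both not well above background without serum. NR0B2, an orphan nuclear receptor, fell 14.8-fold (2 of 5 serum arrays above background) and SNED1 at least 2.65-fold. RAB37, a small GTPase, fell 11.9-fold, SLCO4C1, an organic anion transporter, 10.8-fold, PKNOX2 10.7-fold, P2RX1, an ATP-gated channel, 9.67-fold (2 of 5 serum arrays), RAB17 9.60-fold and GLDN 8.68-fold. Single arrays stood apart for ID3 (repeat 5, high on gelatin in both media), F3 (repeat 5, high with serum), SLCO4C1 (repeat 1, high with serum) and PDK4 (repeat 1, high without serum).

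The median change of all genes was -0.10 with serum on gelatin, and -0.03 with quantile normalisation, -0.02 with normexp and 0.02 in the authors' table, against which the list medians of that comparison stand. Higher genes made up 34.8% of the calls, and 52.9% in the authors' table (1919 higher, 1709 lower). With the block 6893 genes were called (2608 higher, 4285 lower), including all of the 3613. The count was 2163 without the gelatin no-serum array of repeat 2, 2135 without the gelatin serum array of repeat 4 and 5592 without the HDFC no-serum array of repeat 4. It was 1273 and 1617 without repeats 2 and 5, and 6789 from the arrays of the comparison alone. Of the 90 calls of named genes, 75 were kept without each single array, 64 without each repeat and 82 under each other scaling. The call of GLDN ended without 12 of the 20 single arrays and under 1 other scaling.

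On HDFC, cholesterol synthesis fell with serum as well. Of 25 members 17 fell, and 22 fell adjusted over the list alone, with a median of -1.34 (camera adjusted p = 1.8e-25, and 0.0334 with an estimated correlation). FDFT1 fell 2.77-fold (log2 change -1.47 ± 0.18, SE, adjusted p = 0.00088), CYP51A1 2.66-fold and DHCR7, a reductase of the final steps of the pathway, 2.86-fold. Within the 5 slides the median was -1.68, -1.64, -1.11, -0.36 and -1.63, and the list lay low on the HDFC no-serum array of repeat 4 (median deviation -1.11). In fatty acid synthesis 6 of 14 fell, and 9 adjusted over the list alone (median -0.81, camera adjusted p = 7.44e-09, and 0.0426 with an estimated correlation), including ACSS2 (4.68-fold), FADS2 (2.51-fold) and FADS1 (1.83-fold). With the block and an estimated correlation the adjusted p was 0.188 for both lists.

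Smaller parts of other lists changed with serum on HDFC. Of YAP-TAZ targets, F3 (2.07-fold, higher in 4 of 5 repeats) and ASAP1 (1.56-fold) rose, with 9 of 24 higher and 1 lower adjusted over the list alone and 7 higher and 1 lower with the block (median 0.39, camera adjusted p = 5.72e-06, and adjusted p = 0.0721 with an estimated correlation). In ribosome biogenesis RRS1 (1.59-fold) and NOP2 (1.43-fold) rose, with 6 of 29 adjusted over the list alone and 10 with the block (median 0.30, camera adjusted p = 1.94e-08, and adjusted p = 0.107 with an estimated correlation). GINS2 (1.52-fold) was the 1 G1-S gene that rose, with 5 of 35 adjusted over the list alone and 5 with the block (median 0.18, camera adjusted p = 7.79e-05, and adjusted p = 0.322 with an estimated correlation). NEU1 (1.58-fold) and WIPI1 (1.82-fold) fell among 25 autophagy genes, with 5 adjusted over the list alone and 6 with the block (median -0.27, camera adjusted p = 0.00107, and adjusted p = 0.107 with an estimated correlation). Without the HDFC no-serum array of repeat 4 the median was 0.27 for G1-S and -0.16 for autophagy, and without those of repeats 2 and 5 it was 0.09 and 0.12 for G1-S. Without repeats 2 and 5 as a whole the ribosome median was 0.19 each. These 4 lists and those of lipid synthesis kept their camera calls without each single array, each repeat and under each other scaling.

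Calls of 3 more lists on HDFC were less stable. BIRC3, an inhibitor of apoptosis, rose 1.89-fold and TNFAIP3, a feedback inhibitor of NF-kB, 2.41-fold among 4 of 23 NF-kB targets that rose (6 adjusted over the list alone, median 0.24, camera adjusted p = 0.00379, and adjusted p = 0.415 with an estimated correlation), a call lost without repeat 1 (median 0.01, adjusted p = 0.106). That median was 0.04 and 0.12 without the HDFC serum arrays of repeats 1 and 2, and 0.11 without the HDFC no-serum array of repeat 5. Interferon-stimulated genes had a median of -0.42 (camera adjusted p = 0.0107, and adjusted p = 0.415 with an estimated correlation). Limma called 0 of their 28 members over all genes, 4 adjusted over the list alone, 6 at an unadjusted p under 0.05 and 6 with the block. That list's call ended without the HDFC no-serum array of repeat 2 (median -0.33, adjusted p = 0.0886). The mitotic list, with a median of 0.05 (camera adjusted p = 0.0479, and adjusted p = 0.669 with an estimated correlation), lost its call under each other scaling, with the block (0.0557) and without the HDFC no-serum arrays of repeats 2 (0.238) and 5 (0.193) and the HDFC serum arrays of repeats 2 (0.188) and 4 (0.134). Its median was 0.004, 0.009, -0.01 and 0.011 without these arrays in turn. It was 0.135 without the HDFC serum array of repeat 3 (adjusted p = 0.0034), and 0.081 (0.0106) and 0.083 (0.0108) without the HDFC no-serum arrays of repeats 3 and 4. Of its members limma called 0 over all genes and 0 adjusted over the list alone, 5 were higher and 1 lower at an unadjusted p under 0.05, and 3 rose with the block.

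In all, 84 genes rose and 353 fell with serum on HDFC, 225 of them at least 2-fold (37 higher, 188 lower), against 628 with the block (98 higher, 530 lower). From the arrays of this comparison alone limma called 0 genes (2395 at an unadjusted p under 0.05, lowest adjusted p = 0.0879), and without repeat 2 it called 5, FDFT1, CYP51A1, DHCR7, TOB1-AS1 and A_23_P147404, the final 2 chosen after their values were seen. ID3 rose 6.17-fold, and 11.4-fold without the no-serum array of repeat 4. BMPER, a secreted modulator of BMP signals, rose 5.55-fold (well above background on 2 of 5 no-serum arrays), ND6 5.05-fold, IL24, a cytokine, 4.46-fold and PDCD1LG2 4.45-fold (1 of 5 no-serum arrays). IL11 rose 3.80-fold and ADAMTS6 3.19-fold. LYZL4 fell 6.25-fold (1 of 5 serum arrays above background), VEGFD, a lymphangiogenic growth factor, at least 3.57-fold and GABRB1 at least 2.16-fold. TMT1A, a methyltransferase, fell 4.75-fold, ACSS2 4.68-fold, PDGFRB, a receptor for platelet-derived growth factor, 4.08-fold, PIR 3.91-fold and SCNN1A, a subunit of the epithelial sodium channel, 3.82-fold (3 of 5 no-serum arrays and 1 of 5 serum arrays). The calls of LYZL4, GABRB1 and SCNN1A ended under each of the 3 other scalings and without 14, 14 and 16 of the 20 single arrays. Those of ID3, IL11 and F3 were kept under each other scaling and ended without 18, 17 and 16 single arrays. ID3 stood apart on the no-serum array of repeat 4 (high), and F3 and WIPI1 on the serum array of repeat 3 (low). Of the genes called on HDFC, 78 of the 84 rises and 338 of the 353 falls were also called in that direction on gelatin, where 4.5 and 35.7 would be shared by independent lists.

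Higher genes made up 19.2% of the calls on HDFC, against 30.9% with quantile normalisation (137 higher, 307 lower), 32.1% with normexp (153 higher, 324 lower) and 45.6% in the authors' table (181 higher, 216 lower). With the block 896 genes were higher and 1980 lower, including all 437. The count was 1633, 70 and 122 without the HDFC no-serum array of repeats 4, 2 and 5, 289 without the gelatin serum array of repeat 2, and 234 and 108 without the HDFC serum array of repeats 2 and 4. It was 75, 136, 663 and 49 without repeats 1, 3, 4 and 5. Of the 43 calls of named genes, 18 were kept without each single array and 34 under each other scaling. FDFT1, CYP51A1 and DHCR7 were the 3 kept without each repeat.

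Genes changed on HDFC without serum were nearly all called in the same direction with serum on gelatin. Of the 68 genes that rose on HDFC, 67 also rose with serum, including FST, ADAMTS6, PDE1C and F3, and of the 220 that fell, 215 also fell, including SNED1, PKNOX2 and PDK4. Independent lists would share 3.7 and 22.2. Both comparisons use the gelatin no-serum arrays, and over all genes their changes correlated at r = 0.808, with 81.2% of the genes of the same sign. In simulations of unchanged groups with the same layout, both comparisons shared the simulated gelatin no-serum arrays. The median r was then 0.415, with 63.7% of the genes of the same sign. The simulated noise was independent between genes, so these simulations do not give the spread that noise shared between genes would cause. The covariance was 0.212, against 0.0222 for the simulated groups, a difference of 0.19. With the responses taken from different slides, the median covariance over 20 splits was 0.194 (0.139 to 0.235) and the median r was 0.636, against a highest simulated covariance of 0.0019. Without repeat 4, r was 0.869 and the covariance 0.191.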

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

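The tests of low signal, of another group's label, of a stress response, of a single array and of scaling were chosen only after the result was seen, as were the splits of list medians, whereas the test of a ceiling and the splits of gene and list counts were chosen before. For the interaction, however, the splits use the fit to matrix differences within repeats, which was added after the data had been seen.

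The HDFC no-serum array of repeat 4 lay far from the other 4 arrays of its group, since the SD of its deviations from the group mean was 0.975, with a gap of 0.788 of the group's range to the next array, and its median correlation with the group was 0.933, with a gap of 0.86. Low signal is not likely as the whole cause, since in the brightest tercile of the genes the SD was 0.92, 1.86 times the highest of the other 19 arrays (0.494). Its lowest distance to any group mean was 1.15 (to HDFC with serum, against 1.22 to its own group). This was 1.52 times the highest distance of another array from its own group (0.753). That argues against the label of another group on an otherwise typical sample. The array was singled out for lying far from its group, so a wrong label on an outlying sample stays open. The test of distances replaced a ratio of distances to the nearest other group and to its own group (0.938), which did not decide. RNA quality, amplification and a sample from outside the 4 groups stay open, while the design names no biological explanation for 1 array. A test of a stress response of that culture asked for high medians of both the immediate early and the heat shock list. It was negative, since the heat shock list lay at percentile 68.96 of random lists, though 14 of its 14 members were higher. The immediate early list lay at percentile 100, with 23 of 25 members higher. With the 2 lists apart, the test does not exclude a stress response, which stays open too.

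The response of cell-cycle genes to HDFC with serum minus that without had a median of -0.519 for G1-S (adjusted p = 0.0253 with an estimated correlation, but 0.119 with the block as well) and -0.453 for mitosis (adjusted p = 0.0791 with an estimated correlation, with 6 of 100 splits as large). A single array is argued against, since without the HDFC no-serum array of repeat 4 the G1-S median was -0.399. Scaling is argued against too, since that median was -0.452 in the authors' table and -0.459 with quantile normalisation. A ceiling of the signal is argued against by the 12.4% of genes that were brighter than the median G1-S gene on gelatin with serum, with 0 saturated values among G1-S probes. Position on the slide, fixed for each group, stays open, and with it the medium itself, which this design cannot separate from position.

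By camera with the preset correlation, the other lists whose response to HDFC differed between the media were YAP-TAZ targets (-0.269), ribosome biogenesis (-0.292), FOXO targets (0.48), immediate early genes (-0.392), heat shock (-0.267) and the respiratory chain (-0.202, with the direction of the test turned by normexp and in the authors' table). With an estimated correlation none of these calls held (adjusted p = 0.165, 0.348, 0.306 and, for each of the final 3, 0.673). The final 3 also ended without the HDFC no-serum array of repeat 4, with medians of 0.091, -0.078 and -0.01 (adjusted p = 0.721, 0.392 and 0.705).

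Among the levels of named genes, 16 of 304 groups (5.3%) held a sample apart from the others, where chance alone gives about 1 in 20. The gap to the nearest sample, as a share of the range of the 5, was as follows. On gelatin without serum it was 0.767 for AKR1B10 (repeat 5, low), 0.744 for ASB2 (repeat 1, low), 0.739 for FST (repeat 4, low) and 0.752 for ID3 (repeat 5, high). There it was also 0.76 for PDK4 and 0.746 for RBL2 (repeat 1, high) and 0.814 for TP53I3 (repeat 2, high). On HDFC without serum it was 0.732 for CDKN1C and 0.744 for ID3 (repeat 4, high) and 0.854 for CXCL1 (repeat 5, high). On gelatin with serum it was 0.717 for F3 and 0.771 for ID3 (repeat 5, high), and 0.801 for SLCO4C1 and 0.742 for TGIF1 (repeat 1, high). On HDFC with serum it was 0.757 for F3 and 0.789 for WIPI1 (repeat 3, low).

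Of the arrays as a whole, the HDFC serum array of repeat 1 had the most spots marked as outliers in its group (2.53%, gap 0.894). The median correlation with the own group was lowest for repeat 1 on gelatin without serum (gap 0.8) and on gelatin with serum (gap 0.727).

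Chance was weighed with 100 splits of the 10 arrays of each comparison. For HDFC without serum the real split gave 288 genes, the highest other 4, and 1 of 100 splits (the real one) gave as many. With serum the real split gave 0 genes and so did all 100. For serum on gelatin the values were 3613 and a highest other of 1, with 1 of 100 as large. For serum on HDFC they were 437 and 1792, with 5 of 100 as large, and chance cannot be excluded by this count. The 4 other splits above 437 all kept repeat 4 whole on 1 side, the highest with repeats 1 and 5 against 3 and 4. Repeat 4 also holds the outlying HDFC no-serum array, and these splits do not tell a structure by slide from an effect of that array. Among the 10 other splits that parted all 5 pairs, as the real one does, the highest was 7 in the same fit without a block. With the slide as a block the real split gave 2876 genes, and the other splits were not fitted with it. Such splits gave at most 1 gene for HDFC without serum and 0 for serum on gelatin. For the interaction, tested on differences within repeats, the real split gave 3 genes, the highest other 0, and 1 of 100 was as large. That fit was added after the data had been seen. The fit chosen before called 0 genes for the interaction, a count that any split reaches. Of the 3 genes, KANK4 and SNED1 were not well above background on any array with serum.

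The number of gene lists called by camera did not exclude chance in any comparison. The real number, the highest other and the splits of 100 with as many were 11, 15 and 18 for HDFC without serum and 3, 10 and 63 with serum. They were 11, 15 and 26 for serum on gelatin, 9, 15 and 31 for serum on HDFC, and 8, 13 and 32 for the interaction. The median of each called list was also set against the 100 splits, singly and with no adjustment over the lists. On HDFC without serum only the real split was as large for G1-S (0.539, highest other 0.5) and ribosome biogenesis (0.368, highest other 0.366). There 2 of 100 were as large for YAP-TAZ targets (0.397, highest other 0.428), mitosis (0.408, 0.41) and FOXO targets (0.569, 0.581). Chance was not excluded there for interferon-stimulated genes (6 of 100), fatty acid synthesis (8), immediate early genes (11), heat shock (33), cholesterol synthesis (36) and the respiratory chain (68). On HDFC with serum 3 of 100 were as large for YAP-TAZ targets, 19 for ribosome biogenesis and 31 for immediate early genes. Within repeats 1 to 5 the ribosome median with serum was 0.181, 0.234, 0.136, 0.051 and 0.123. That of the YAP-TAZ list was 0.1, 0.215, 0.216, 0.214 and 0.134. With serum on gelatin only the real split was as large for 9 of the 11 lists, such as cholesterol synthesis (1.562 in size, highest other 1.114), while 2 were for autophagy and 32 for the respiratory chain. These 9 include the control list of fibroblast markers (1.006, highest other 0.882). The same held for the control list of luminal and basal markers (0.433, highest other 0.396), which camera did not call there. With serum on HDFC only the real split was as large for cholesterol synthesis (1.344, highest other 1.196), fatty acid synthesis, YAP-TAZ targets, interferon-stimulated genes and autophagy, while 9 were for ribosome biogenesis, 15 for NF-kB targets, 16 for G1-S and 65 for mitosis. For the interaction only the real split was as large for G1-S (0.519, highest other 0.452), and 4 were for YAP-TAZ targets. Heat shock had 0.282 with outlier values filled in, as in the splits, and a highest other of 0.275, but 0.267 in size with these values left out, so that chance is not excluded for it. Nor was it for the interaction of mitosis (0.453, highest other 0.505), ribosome biogenesis and FOXO targets (6 of 100 each), the respiratory chain (32) and immediate early genes (61).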

How the results depend on the processing

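Fits with the block and without the HDFC no-serum array of repeat 4, the fit to matrix differences, and the lists under normexp and under omissions were chosen only after the result was seen, and the other alternatives before. Of 5638 values of 162 named results, 4588 kept direction and side of the threshold, 1050 lost the call and 0 turned. Of 1344 values of 42 list results, 1200 kept both, 131 lost the call and 13 turned. The repeat block changed no other call than those given. Signal over background limits genes dim in 1 group, whose change is then a bound, and a filter changes which of them are tested.

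The genes changed on HDFC without serum (288) numbered 463 with normexp, 133 without a filter, 151 with a strict filter, 2807 with a fixed and 2768 with a random block, 10 from the arrays of the comparison alone, 495 with array weights, and 4216 with the block and without the HDFC no-serum array of repeat 4. With serum (0, limma; 1063 unadjusted) they numbered 2, 5, 4 and 95 with the fixed block, random block, array weights and block without that array. For serum on gelatin (3613) they numbered 6893, 6861, 8914 and 10841 in the same order and 6789 from the arrays of the comparison alone. For serum on HDFC (437) the order gave 2876, 3015, 1434 and 4556, with 211 without a filter and 0 from the arrays of the comparison alone (limma). The interaction (0) had 2 genes with quantile normalisation and in the authors' table, 1 with the fixed block, the random block and the block without that array, and 3 by matrix differences. The blocks lower the standard error. A fit of the arrays of a comparison alone uses the spread of its own groups. That spread was largest for HDFC without serum (median SD 0.508) and smallest for gelatin with serum (0.269). Whether this alone moved those counts, and the cause for the other settings, was not tested.

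Leaving out samples gave 0 to 792 genes for HDFC without serum (0 without repeat 1), 0 to 1 with serum, 1273 (repeat 2) to 5592 for serum on gelatin, and 0 to 1 for the interaction. For serum on HDFC it gave 5 (repeat 2) to 1633, the 5 being FDFT1, CYP51A1, DHCR7, TOB1-AS1 and A_23_P147404, chosen after their values were seen. The correlation of the matrix responses (0.527) was 0.317 without a filter, where dim probes enter, and 0.42 to 0.584 under omissions. Of 42 list calls, 10 held with an estimated correlation, and 38 to 48 were made under omissions. With the block and an estimated correlation camera called 0 of the 30 lists in each of the 5 comparisons.

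The respiratory chain list turned on HDFC without serum to -0.056 with quantile normalisation, -0.075 in the authors' table and -0.078 with normexp, with serum on gelatin to -0.025, -0.055 and -0.043, and for the interaction to -0.009 in the authors' table and -0.01 with normexp. The interaction of the immediate early genes turned to 0.091 without the HDFC no-serum array of repeat 4, 0.106 with the block as well and 0.116 without repeat 4, the highest under omissions, the lowest being -0.596. For cholesterol synthesis on HDFC without serum the test turned against a median of -0.041 with the block and without that array and -0.065 without repeat 4, the highest under omissions, the lowest being -0.457. The cause was not tested.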

Other observations

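The test of a stress response, that of a fixed fraction of the serum response and that of slide position were chosen only after the result was seen, and that of the shared arrays before.

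Of 20 integrins and collagen receptors 4 fell with serum on gelatin, among them DDR1, a collagen receptor kinase (2.23-fold), ITGA10, a collagen-binding integrin subunit (3.79-fold), and ITGB4, a laminin-binding one (4.01-fold). Adjusted over the list alone 4 were lower and 1 higher, and with the block 8 and 2. On HDFC without serum ITGA10 fell 2.78-fold, and 5 were lower and 1 higher adjusted over the list alone, against 6 and 1 with the block. The call of ITGA10 ended there under 2 of the 3 other scalings and without 17 of the 20 single arrays. Camera did not call the list against other genes (adjusted p = 0.127 on gelatin with serum and 0.139 on HDFC without serum). Among 36 secreted proteases and inhibitors, 5 rose and 7 fell with serum on gelatin (6 and 10 adjusted over the list alone), with ADAMTS6 5.84-fold higher, and CTSK, a collagen-degrading cathepsin (2.14-fold), and TIMP4, a metalloprotease inhibitor (2.01-fold), lower. Fry for change in either direction gave an adjusted p of 1.27e-08 for them. On HDFC without serum, the collagenases MMP14 (log2 change -0.36, adjusted p = 0.515) and MMP1 (0.23, 0.848) and the invadopodia scaffold CTTN (0.01, 0.984) did not pass the test. Of 30 genes of invadopodia and core actin regulation limma called 0 there, 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone and 2 lower with the block, with a median of 0.06 and a mean of -0.01. With serum on gelatin, SH3PXD2A (2.29-fold, adjusted p = 0.0263) and SH3PXD2B (1.76-fold), scaffolds of invadopodia, fell and ACTR2, a subunit of the Arp2/3 complex, rose 1.61-fold. These 3 members also passed adjusted over the list alone, 3 were lower and 2 higher with the block, and camera did not call the list (median -0.05, adjusted p = 0.546). Their calls ended without 5, 7 and 6 of the 20 single arrays, and those of SH3PXD2B and ACTR2 under 3 and 2 of the 3 other scalings.

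Another list held D cyclins and CDK inhibitors together with CDK4, CDK6, RB1, RBL2, CCNG1 and CCNG2. Of its 14 members tested, 5 fell with serum on gelatin (6 adjusted over the list alone) and 2 on HDFC (4 adjusted over the list alone and 4 with the block). CCNG2, an atypical cyclin of growth arrest, fell 4.15-fold and 2.97-fold, and CDKN1C, a CDK inhibitor, fell 2.99-fold on HDFC. By fry the list moved down on balance (adjusted p = 6.77e-06 on gelatin and 2.65e-05 on HDFC), whereas camera against other genes gave 0.127 and 0.0529. Of 20 NRF2 targets and metallothioneins 6 fell with serum on gelatin (6 adjusted over the list alone), including the reductases AKR1B10 (3.67-fold) and AKR1C1 (3.58-fold), though the median of the list was 0.01 and its mean -0.33 (camera direction down, adjusted p = 0.445). Of 29 growth factors and receptors 3 rose and 5 fell (5 and 5 adjusted over the list alone), with FGF5 3.24-fold higher and PDGFRB 4.74-fold lower. Their median was -0.19, while the camera direction was up (adjusted p = 0.977). The respiratory chain list was called with serum on gelatin (median 0.13, adjusted p = 0.0467, and 0.739 with an estimated correlation), but its direction flipped with quantile normalisation (-0.03). That call ended without the gelatin no-serum arrays of repeats 1 (0.217) and 5 (0.0631), the HDFC no-serum array of repeat 5 (0.0508) and the gelatin serum arrays of repeats 2 to 5 (0.0519, 0.0596, 0.127 and 0.0634). Its median was 0.04 without the first of these arrays and 0.09 to 0.14 without the others, while it was 0.21 without the gelatin serum array of repeat 1 (adjusted p = 0.0122).

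Markers of leukocytes, endothelium and fibroblasts, and of luminal and basal breast epithelium, served as controls. With serum on gelatin, limma called 0 of 13 leukocyte markers (1 at an unadjusted p under 0.05, and 0 adjusted over the list alone or with the block), 2 of 7 endothelial markers (VWF and PECAM1, lower) and 3 of 10 luminal and basal markers (TP63, FOXA1 and ELF3, lower, and 5 with the block). Of 5 fibroblast markers PDGFRB and COL1A1 fell, with a median of -1.01 for the list (camera adjusted p = 0.0322, and 0.102 with an estimated correlation). That call ended without the gelatin serum array of repeat 5 (median -0.73, adjusted p = 0.0634) and with quantile normalisation. Fibroblast, endothelial, leukocyte and luminal markers were not called by camera on HDFC without serum (adjusted p = 0.106, 0.944, 0.809 and 0.213).

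On the HDFC no-serum array of repeat 4, compared with the mean of the other 4 arrays of its group, FOS lay 5.10, FOSB 6.69, EGR1 3.45 and ATF3 5.04 higher (log2), and the heat shock genes HSPA6 8.81 and HSPA1A 3.45 higher. HMGCS1, the synthase that feeds cholesterol synthesis, changed by -3.35. These genes were chosen after their values were seen. An acute stress response of that sample may be a candidate explanation. The median of the immediate early list (1.72) lay at percentile 100 of 10000 random lists matched on level, but that of the heat shock list (0.99, with 14 of 14 members higher) lay at percentile 68.96, so that the test, which asked for both medians in the top 5% of such lists, was negative. Of 13 leukocyte markers 10 lay higher on that array, with a median deviation of 1.17 (percentile 99.91). CD74 lay at -1.70 there against -2.92 ± 0.38 (SD, n = 4) on the others, TYROBP lay 0.36 higher, LYZ changed by -1.62 and PTPRC was not well above background there, and these 4 markers were also chosen after their values were seen.

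Genes changed on HDFC without serum moved the same way with serum on gelatin. The shared gelatin no-serum arrays are not likely to be the whole cause, since with the responses taken from different slides the median covariance was 0.194. For HDFC as a fixed fraction of serum for all genes, the ratio of the HDFC to the serum response was 0.76 ± 0.38 for the G1-S list and 0.22 ± 0.42 for the cholesterol list (SD, n = 5). The mean difference of 0.544 ± 0.25 (SD) was positive in 5 of 5 repeats, which argues against such a fraction for this pair of lists. The cholesterol mean was the lowest of the lists taken and the pair was chosen after the result was seen, so that this choice may overstate the difference. The ratio was 1.00 ± 0.67 for FOXO targets, 0.74 ± 0.60 for ribosome biogenesis, 0.71 ± 0.38 for interferon-stimulated genes and 0.69 ± 0.44 for YAP-TAZ targets (SD, n = 5). The ratio was 0.67 ± 0.53 for mitosis (-0.199 to 1.059 over the repeats) and 0.42 ± 0.40 for fatty acid synthesis (0.118 to 1.075), and a division between growth genes and lipid synthesis was not tested. Position on the slide, 1 per group, cannot be told apart from the conditions and stays open.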
